A study of Lactuca sativa with 72 samples.

How the data were processed

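Gene and transcript tables of 72 lettuce libraries were used, covering leaf and root, 2 conditions, 6 treatments and 3 biological replicates per group. Per the labels, RNA was extracted with a NucleoSpin plant kit, stranded libraries were made and 150 bp reads were sequenced on the DNBseq platform. Reads were aligned with HISAT2, per the submitters' processing notes. The counting tool, genome build and annotation are not given in the sources used here. The deposited tables hold expected counts per gene and per transcript, not normalized, of which 4.72% of gene values are not whole numbers. They were rounded to whole numbers before testing. Transcript values summed to the gene values within 0.04 for all 28669 genes, so the gene table was used throughout. Every column of values was matched to a sample by its name.

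All 28669 gene identifiers matched the reference gene table of the assembly Lsat_Salinas_v11, which was used only for names. Of these, 106 genes have a symbol other than the identifier, 70 of them chloroplast-encoded and 36 mitochondrial, and 2 nuclear genes have a synonym. With no gene descriptions, none of the 39 gene lists fixed before the data were examined, cytokinin synthesis among them, matched any gene, and their tests were not run. Lists of chloroplast-encoded genes were made from the gene symbols after the data were examined, and tested with camera (limma 3.58.1) on log2 CPM. Markers of other organs were instead taken from the control plants, as 85 leaf and 57 root genes with at least 100 CPM and at least 1000 times the level of the other organ.

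Each tissue was fitted in a single model of 12 groups and 36 libraries with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood test. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called, with no limit on fold change. Counts at an unadjusted p under 0.05 are given for some contrasts. On average a share of 0.05 of unchanged genes passes that limit by chance, so such a count alone shows no change. Standard errors of log2 changes were taken from the test statistic, as the absolute change over the square root of F. Contrasts were salt against normal in control plants, each treatment against the control of its condition, each combination against its components under salt, the departure of each combination from the sum of its components under salt, and the interaction of salt with treatment. The mean salt effect over the 6 treatments was added after the data were examined. Levels are TMM-normalised CPM, except the summed gene sets, which use CPM of the full library.

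Genes were named by a rule fixed before the data were examined. Among called genes with a mean of at least 1 CPM and no overlap between the compared libraries, the 10 largest rises and 10 largest falls were taken for salt in control plants and for each combination against the salt control, and 3 of each for other pairwise comparisons. A part of them is printed. Non-overlap of 3 against 3 libraries occurs for 10% of unchanged genes by chance. A fold change against a group with no read is given as a bound, from 3 counts over that group. The bound is for the mean of the other group, and single libraries of that group can lie far below its mean.

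On simulated counts for BS+PGPB against control under salt, with 200 changed genes, the procedure recovered 40% of genes changed 2-fold and 75% of genes changed 4-fold in leaf (21140 genes) and 58% and 81% in root (22900 genes). It called 6 unchanged genes in leaf and 3 in root. The simulated counts were drawn independently for each library, and the changed genes had a mean of at least 1 CPM. Structure shared between real libraries was not simulated, so these rates need not hold for the real data.

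No pair of replicates agreed within sampling noise: the smallest chi-square per gene was 9.51. Replicate numbers are shared between groups in the labels. The deviations of same-numbered libraries from their group means correlated above 0.1 in all 3 pairs in 5 of 30 pairwise comparisons: salt against normal in leaf control plants, both combinations against BS in salt-stressed leaf, and BS+AMF against BS and against AMF in salt-stressed root. The block is treated as pairing those comparisons only. The alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, each library left out in turn and, added after the data were examined, a fit of the compared groups alone. Counts of photosynthesis genes in 3 leaf contrasts were also recomputed with each library left out, added after the data were examined. The functions of genes outside the chloroplast lists, and with them cytokinin synthesis, were not analysed here.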

Results

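Leaf and root RNA was sequenced from greenhouse lettuce (Lactuca sativa) to compare a non-microbial biostimulant with its combinations with microorganisms under salt stress. The 6 treatments were an untreated control, the product Calbio (BS), a bacterial strain (PGPB), an arbuscular mycorrhizal fungus (AMF, a fungus that lives in symbiosis with roots), BS+PGPB and BS+AMF. A list of treatments in the labels spells the product Valbio for BS+AMF, while the own labels of the BS+AMF samples give Calbio, which was used. Each was grown under normal and salt stress conditions, and leaf and root were sampled, which gave 24 groups of 3 biological replicates and 72 libraries. Total counts ran from 14.8 to 18.3 M (mega) per leaf library and from 13.9 to 17.4 M per root library. After the filter on low counts, 21311 genes were tested in leaf and 23103 in root. Nearly every gene is named by an identifier that carries no function, so genes are described by level and change alone.

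The organs differed in how far the groups explained the variation. In root, the leading principal component held 29.2% of the variance and 74.2% of it lay between groups. On it, BS+AMF libraries had scores of 15.5 to 110.3 and libraries not given the fungus -54.8 to 34.6. AMF libraries lay between -20.8 and 58.3, except normal AMF replicate 3 at -43.2. The next component held 13.4%, with 78.4% of it between groups, and BS+PGPB libraries had scores of -71.9 to -31.2 on it. Salt PGPB libraries were at -6.53, -40.7 and -54.1 and salt BS replicate 2 at -68.4, and no other library lay below -15.2. In leaf, the leading component held 30.8% of the variance and only 32.5% of it lay between groups. With 12 groups of 3 libraries, about this share is expected when groups do not differ. Replicates lay apart in several leaf groups. In the normal control, replicates 2 and 3 correlated at 0.981 (Pearson, log2 CPM) and with replicate 1 at a mean of 0.882, and the scores on the leading component were -53.1 for replicate 1 and 110.6 and 97.6 for the pair. In salt BS+AMF, replicates 1 and 2 correlated at 0.958 and with replicate 3 at 0.901 and 0.856, the lowest of all leaf replicate pairs, with scores of -60.0, -101.1 and 75.7. Salt AMF had scores of -0.572, -105.5 and -4.19, and salt BS+PGPB of -2.73, 1.97 and 86.4. The 85 genes most leaf-predominant in control plants summed to a median of 106600 CPM in leaf libraries and to at most 53.8 CPM in root libraries. They summed to 102400 CPM in normal control replicate 1 and to 70460 and 76910 CPM in replicates 2 and 3.

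**Figure D1:**
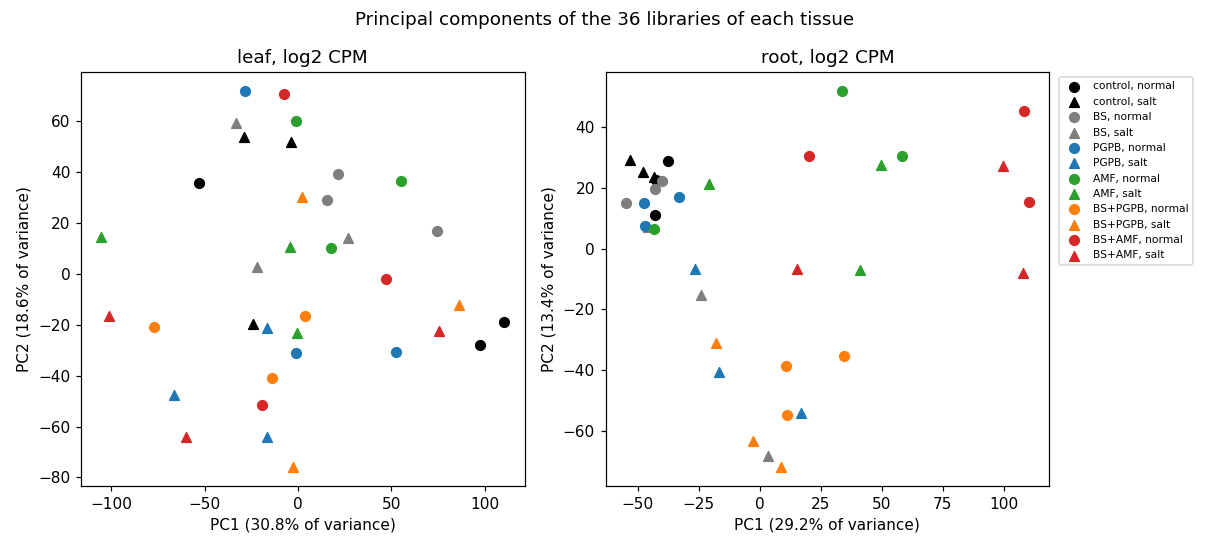
Principal components of log2 CPM for the 36 leaf and 36 root libraries, with PC1 on the horizontal and PC2 on the vertical axis, colour for treatment, circles for normal and triangles for salt. In root, BS+AMF libraries have PC1 scores of 15.5 to 110.3, libraries not given the fungus -54.8 to 34.6, and AMF libraries overlap both.

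Salt alone left no gene past the threshold in control plants of either organ. In leaf, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with 3301 at an unadjusted p under 0.05 and 12 called by DESeq2. In root it called 0 genes, with 1962 at an unadjusted p under 0.05 and 2 called by DESeq2. The leaf count was 3810 without normal control replicate 1, which leaves the pair of replicates 2 and 3, and 0 without any other of the 6 libraries. Averaged over all 6 treatments, a contrast added after the data were examined, salt changed 1021 root genes, of which 635 rose and 386 fell, by a median of 0.31 on the log2 scale (1742 called by DESeq2). A large change in 1 treatment can move this mean, so these genes need not have changed in each treatment. In leaf that contrast called 0 genes, with 3764 at an unadjusted p under 0.05. It called 33 genes with DESeq2 size factors, 608 with DESeq2 and 3 with the replicate block. Leaving out 1 library gave a leaf count of 54 without normal AMF replicate 1, 40 without normal BS+PGPB replicate 1, 1187 without normal control replicate 1, 218 without salt AMF replicate 1, 298 without normal BS replicate 2, 21 without salt BS replicate 2, 18 without salt BS+PGPB replicate 2, 61 without normal BS+AMF replicate 3, 157 without normal PGPB replicate 3, 269 without salt BS+AMF replicate 3, 9 without salt control replicate 3 and 39 without salt PGPB replicate 3. The root count of the same contrast was 1558 without salt PGPB replicate 1, 642 without salt PGPB replicate 2 and 615 without salt BS+PGPB replicate 3.

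In root under salt, the combination BS+PGPB changed 4744 genes against the salt control, with 2762 higher and 1982 lower. LOC111886355 rose to 27.2 ± 19.4 CPM from 0.0601 ± 0.000459 CPM (SD, n = 3 in each group), a log2 change of 8.65 with a standard error of 2.38 and an edgeR adjusted p of 0.0118. Its control level equals that of 3 counts over the control group, so the size of this change rests on few reads. The small control SD is no measure of precision there. LOC111894200 rose to 14.9 ± 5.55 CPM from 0.261 ± 0.0344 CPM (SD, n = 3, edgeR adjusted p = 8.12e-07). LOC111902035 fell to 26.6 ± 4.59 CPM from 303 ± 67.2 CPM (SD, n = 3, edgeR adjusted p = 2.32e-09), and LOC111916411 fell to 0.338 ± 0.094 CPM from 12.2 ± 4.77 CPM. The 10 largest rises lay between 5.17 and 8.65 on the log2 scale and the 10 largest falls between -5.52 and -3.51. Leaving out 1 library gave 2467 without BS+PGPB replicate 1, 2630 without control replicate 2, 2854 without BS+PGPB replicate 3 and 2781 without control replicate 3.

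The combination BS+AMF changed 3522 root genes under salt, with 2315 higher and 1207 lower. Of its 10 largest rises, 9 were genes with no read in any salt control library. LOC111921849 reached 220 ± 186 CPM (SD, n = 3), at least 3660-fold higher than 3 counts over the control group would give, and LOC111902598 reached 130 ± 109 CPM, at least 2170-fold higher. The other, LOC111904359, rose to 319 ± 259 CPM from 0.0202 ± 0.035 CPM (SD, n = 3, edgeR adjusted p = 0.000224), a control level below 3 counts over the group. Among the falls, LOC111902035 dropped to 22.5 ± 4.22 CPM and LOC111898118 to 34.7 ± 6.79 CPM from 317 ± 37.3 CPM (SD, n = 3, edgeR adjusted p = 1.59e-06). The count was 2252 without BS+AMF replicate 1, 1726 without BS+AMF replicate 2, 1762 without control replicate 2 and 1829 without control replicate 3.

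Each component given alone also changed root genes under salt. PGPB changed 2574 genes, 1666 higher and 908 lower, with LOC111914027 rising to 3.55 ± 1.40 CPM from 0.02 ± 0.0347 CPM and LOC111888057 falling to 1.00 ± 0.742 CPM from 17.9 ± 6.22 CPM (SD, n = 3, edgeR adjusted p = 0.00122 and 0.000175). The control level of LOC111914027 lies below 3 counts over that group. BS changed 1402 genes, 857 higher and 545 lower, and LOC111893813 fell to 12.8 ± 6.27 CPM from 103 ± 37.4 CPM (SD, n = 3, edgeR adjusted p = 0.00651). AMF changed 777 genes, 573 higher and 204 lower, and LOC111883556 rose to 16.6 ± 15.1 CPM, at least 277-fold above 3 counts over a control group with no read. A fit of the compared groups alone, added after the data were examined, called 0 genes for BS (2621 by DESeq2), 1102 for PGPB and 236 for AMF (1695 by DESeq2). The BS count was 919 without control replicate 1, 82 without BS replicate 2, 71 without control replicate 2 and 250 without control replicate 3. For PGPB it was 1242 without control replicate 2, 1280 without PGPB replicate 2, 1290 without control replicate 3 and 1371 without PGPB replicate 3. For AMF it was 164 without AMF replicate 1, 388 without AMF replicate 2, 42 without control replicate 2 and 116 without control replicate 3.

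Under normal conditions, most genes that changed in root did so with the combinations. BS+PGPB changed 4253 genes, 2239 higher and 2014 lower, and BS+AMF 3324, 1635 higher and 1689 lower. LOC111916411 fell to 0.201 ± 0.117 CPM with BS+PGPB and to 0.262 ± 0.318 CPM with BS+AMF, from 11.4 ± 5.91 CPM in the control (SD, n = 3, edgeR adjusted p = 2e-06 and 4.48e-06). LOC111901238, with no read in the normal control, reached 171 ± 204 CPM with BS+AMF, at least 2740-fold above 3 counts over that group. PGPB alone changed 11 genes, all higher, among them LOC111895709 at 123 ± 11.2 against 35.3 ± 8.69 CPM (SD, n = 3, edgeR adjusted p = 0.01). AMF alone changed 14 genes, 13 higher and 1 lower, and LOC111907939 rose to 30.8 ± 13 from 5.54 ± 1.71 CPM (SD, n = 3, edgeR adjusted p = 0.0114). BS alone changed 0 genes by edgeR, with 910 at an unadjusted p under 0.05 and 3 called by DESeq2. The 910 lie below a share of 0.05 of the 23103 genes tested. Tested over all genes, the effect of a component differed between salt and normal conditions in 2 genes for BS, 38 for PGPB and 0 for AMF. The fit of the compared groups alone gave 0 genes for PGPB (52 by DESeq2), 1 for AMF (283 by DESeq2) and 1523 for BS+AMF, and the PGPB count was 6 with no filter on low counts and 7 with the replicate block. Leaving out 1 library, BS+PGPB gave 2670 without BS+PGPB replicate 2, 2826 without BS+PGPB replicate 3 and 2199 without control replicate 3. BS+AMF gave 1864 without control replicate 1, 1698 without BS+AMF replicate 2 and 1796 without control replicate 2. PGPB gave 0 without control replicate 1 or 2, 0 without PGPB replicate 1, 7 without PGPB replicate 2, 4 without control replicate 3 and 40 without PGPB replicate 3. AMF gave 2 without control replicate 1, 5 without AMF replicate 2, 0 without control replicate 2, 99 without AMF replicate 3 and 9 without control replicate 3.

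**Figure D2:**
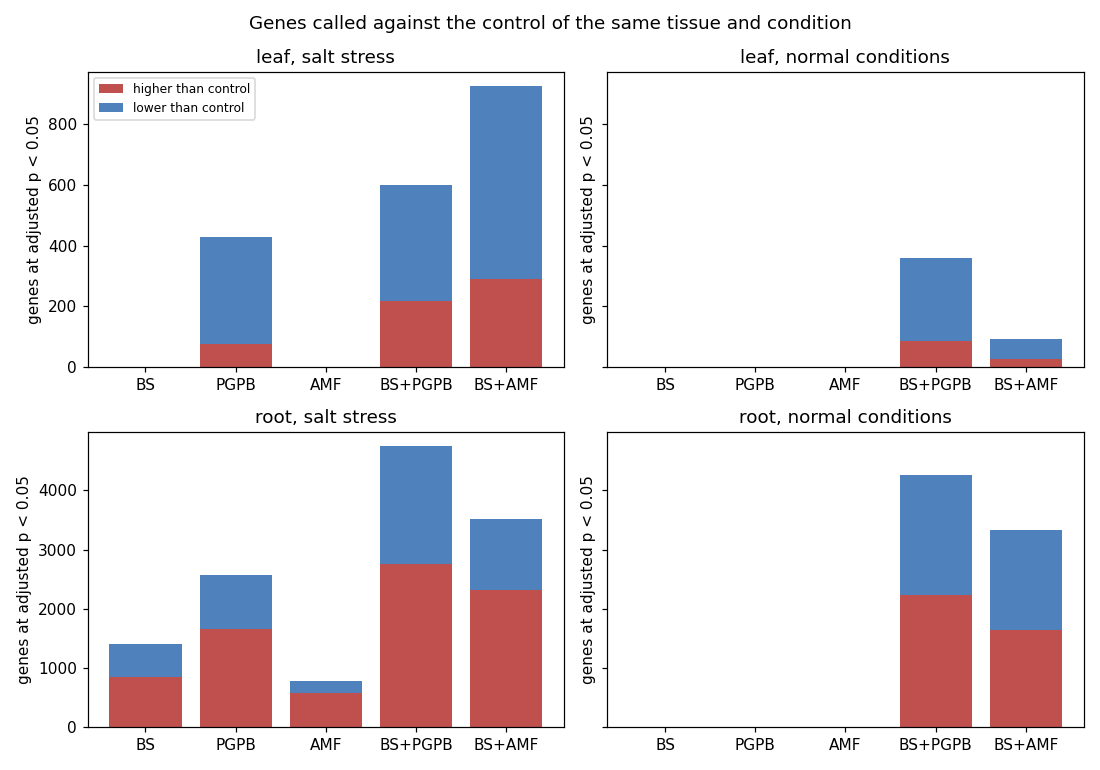
Number of genes at an adjusted p under 0.05 against the control of the same tissue and condition, stacked as higher (red) and lower (blue), with 3 libraries per group and separate vertical scales for leaf and root. Root counts reach 4744 for BS+PGPB under salt, and the 11 and 14 genes of PGPB and AMF in normal root are too few to show at this scale.

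Many root genes changed with a combination in both conditions, a comparison of separate libraries with separate controls. For BS+PGPB, 1362 genes were higher in both conditions where independent lists would share 268, 817 were lower in both where 173 would be shared, and 7 went in opposite directions. For BS+AMF, 1040 were higher in both against 164, 546 were lower in both against 88.2, and 2 were opposite. The interaction of salt with treatment over all 6 treatments called 9 root genes. In each, the means of salt PGPB and of both combinations in both conditions lay apart from the means of the other 7 groups. LOC111877455, for example, was at 67.3 ± 5.75 CPM in normal PGPB and 150 ± 31.1 CPM in salt PGPB, against 60.5 ± 5.23 and 63.7 ± 5.35 CPM in the normal and salt controls (SD, n = 3, edgeR adjusted p of the interaction = 0.00543). The summed level of the 57 root-predominant genes was also lowest in the 5 groups set apart above, with group means of 11050 to 13160 CPM against 14160 to 18740 CPM in the other 7. Single libraries overlapped, with 15640 CPM in normal BS+PGPB replicate 3 and 12650 CPM in normal BS replicate 2. Those 57 genes were chosen for a high level in normal control roots, a group among the 7. The interaction count was 2 without normal PGPB replicate 2, 14 without salt BS replicate 2 and 3 without salt PGPB replicate 2, and DESeq2 called 431. In leaf the interaction called 1 gene, LOC111879943 (edgeR adjusted p = 0.0426), against 0 with no filter on low counts, 0 with the replicate block and 29 by DESeq2.

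**Figure D3:**
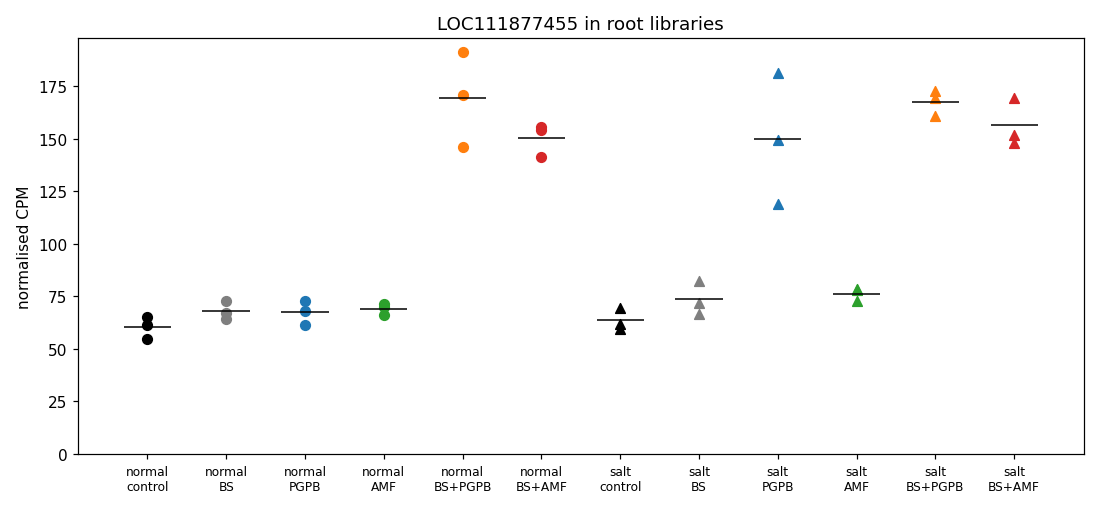
Normalised CPM of LOC111877455 in each root library (points), by group, with a line at the mean of 3 libraries. Salt PGPB and the BS+PGPB and BS+AMF groups of both conditions have means between 149.9 and 169.3 CPM, and the other 7 groups have means of at most 76.3 CPM.

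A set of 101 genes had higher levels in most AMF-treated roots than in roots not given AMF. Chosen after the data were examined, and on the normal-condition libraries alone, 101 genes had a mean of at least 5 CPM with AMF and at least 10 times the highest library without it. In the salt libraries, not used to choose them, 100 of the 101 had a mean with AMF above every library without it, and 93 were at least 10 times higher. Their summed level was 70.5 to 3811 CPM in the 6 salt libraries with AMF and at most 33.6 CPM in the 12 without (two-sided exact permutation p = 5.39e-05, the smallest this design can give). The same rule found 0 genes for PGPB and 1 for BS in root. Levels varied widely among AMF-treated roots, from 53.2 CPM in normal AMF replicate 3 and 70.5 CPM in salt AMF replicate 3 to 5919 CPM in normal BS+AMF replicate 3. Both of the low libraries lay below normal BS+PGPB replicate 2, which was not given AMF. That library reached 108.6 CPM, the highest of the 24 libraries without the treatment, whose median was 9.97 CPM. Whether fungus was present in a root is not given by the treatment label.

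**Figure D4:**
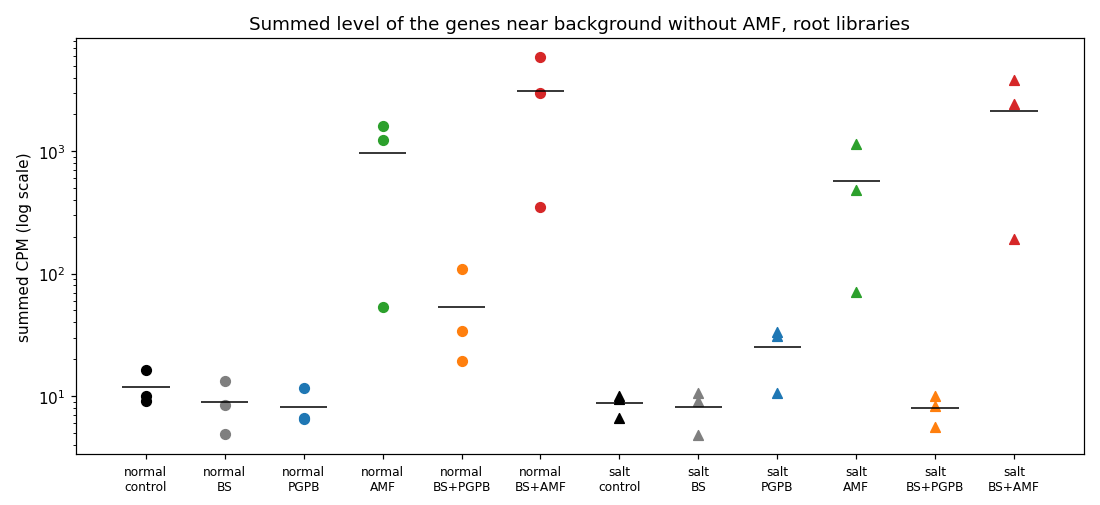
Summed CPM (logarithmic axis) of the 101 genes in each root library, by group, with a line at the mean of 3 libraries. AMF and BS+AMF libraries lie between 53.2 and 5919 CPM, and libraries not given the fungus at or below 108.6 CPM.

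Set directly against its components in salt-stressed root, BS+PGPB differed from BS in 289 genes, 175 higher and 114 lower. From PGPB it differed in 0 genes by edgeR, with 760 at an unadjusted p under 0.05 and 20 called by DESeq2. The 760 lie below a share of 0.05 of the 23103 genes tested. LOC111907267 was at 12.2 ± 2.3 CPM with BS+PGPB and 1.14 ± 0.296 CPM with BS (SD, n = 3, edgeR adjusted p = 7.9e-08), and LOC111916411 at 0.338 ± 0.094 against 8.98 ± 3.45 CPM. BS+AMF differed from BS in 644 genes, 487 higher and 157 lower, and from AMF in 101, 63 higher and 38 lower. LOC111918659 was at 38.8 ± 12.3 CPM with BS+AMF and 2.89 ± 0.84 CPM with AMF (SD, n = 3, edgeR adjusted p = 1.18e-06), and LOC111898118 at 34.7 ± 6.79 against 286 ± 79.7 CPM. The fit of the compared groups alone gave 7 genes for BS+PGPB against BS, 3 for BS+AMF against BS and 19 for BS+AMF against AMF, where DESeq2 called 779, 1035 and 305. When 1 library was left out, BS+PGPB against BS gave 119 without BS replicate 1, 140 without BS+PGPB replicate 1, 148 without BS replicate 2 and 76 without BS+PGPB replicate 3. The count for BS+AMF against BS was 270 without BS replicate 1, 199 without BS+AMF replicate 1, 165 without BS replicate 2, 370 without BS+AMF replicate 2 and 309 without BS replicate 3. That for BS+AMF against AMF was 42 without AMF replicate 1, 67 without AMF replicate 2, 33 without BS+AMF replicate 2 and 159 without BS+AMF replicate 3.

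By edgeR's adjusted p, the combined effect under salt departed from the sum of its components in few root genes. For BS+AMF, 101 genes departed, 46 above and 55 below the sum on the log2 scale, with 3694 at an unadjusted p under 0.05. LOC111907267 was at 0.883 ± 0.19 CPM in the control, 1.14 ± 0.296 with BS, 1.38 ± 0.275 with AMF and 13.3 ± 3.31 with BS+AMF (SD, n = 3, edgeR adjusted p = 0.0015). LOC111898118 was at 317 ± 37.3, 363 ± 134, 286 ± 79.7 and 34.7 ± 6.79 CPM in the same order. Both are also among the root interaction genes, and salt PGPB, given no AMF, had means of 8.75 and 44.55 CPM for them. For BS+PGPB, 2 genes departed, LOC111880935 and LOC111906087, with 1959 at an unadjusted p under 0.05. LOC111880935 was at 35.8 ± 7.94 CPM in the control and close to 100 CPM in every treated group, 94.8 ± 13 with BS, 101 ± 15.7 with PGPB and 99.4 ± 14 with both (SD, n = 3, edgeR adjusted p = 0.00392). These genes were taken by smallest p after the values were seen. DESeq2 called 604 genes for BS+AMF and 70 for BS+PGPB, and the replicate block 1 for BS+PGPB. The BS+AMF count was 35 without AMF replicate 1, 32 without BS+AMF replicate 1, 56 without AMF replicate 2, 32 without BS replicate 2, 29 without control replicate 2, 55 without AMF replicate 3, 259 without BS replicate 3, 66 without BS+AMF replicate 3 and 37 without control replicate 3. For BS+PGPB it was 1 without BS replicate 1 or 2, 1 without BS+PGPB replicate 1 or 2 or 3, 7 without control replicate 1, 1 without control replicate 2 or 3 and 1 without PGPB replicate 3.

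In leaf under salt, falls outnumbered rises. BS+AMF changed 927 genes, 291 higher and 636 lower, BS+PGPB 601, 218 higher and 383 lower, and PGPB 429, 76 higher and 353 lower. LOC111876661 fell from 165 ± 94.2 CPM in the control to 36.3 ± 15 with BS+AMF, 34.7 ± 1.71 with BS+PGPB and 39.1 ± 4.18 with PGPB (SD, n = 3, edgeR adjusted p = 0.00678, 0.0126 and 0.0151). LOC111878943 rose to 8.65 ± 5.38 CPM with BS+AMF from 0.479 ± 0.355 CPM, and LOC111879659 to 8.75 ± 4.88 CPM with BS+PGPB from 1.40 ± 0.633 CPM (SD, n = 3, edgeR adjusted p = 0.0219 and 0.0453). BS changed 0 genes by edgeR (452 at an unadjusted p under 0.05, 3 by DESeq2), as did AMF (932 and 3). Both 452 and 932 lie below a share of 0.05 of the 21311 genes tested. Fitted with the compared groups alone, PGPB, BS+PGPB and BS+AMF called 0 genes each, where DESeq2 called 996, 1471 and 1679. Leaving out 1 library, PGPB gave 51 without control replicate 1, 190 without PGPB replicate 1, 0 without control replicate 2, 1 without PGPB replicate 2 and 0 without PGPB replicate 3. BS+PGPB gave 0 without BS+PGPB replicate 1 or 3, 0 without control replicate 1, 302 without BS+PGPB replicate 2 and 32 without control replicate 2. BS+AMF gave 119 without BS+AMF replicate 1, 145 without control replicate 1, 382 without BS+AMF replicate 2 and 224 without control replicate 2. BS gave 1 without BS replicate 1 or 2 and 1 without control replicate 3, and AMF 1 without control replicate 3.

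Against its components in salt-stressed leaf, BS+PGPB differed from BS in 451 genes, 103 higher and 348 lower, and BS+AMF from BS in 907, 199 higher and 708 lower. LOC111915172 was at 3.29 ± 0.718 CPM with BS+PGPB and 3.37 ± 1.25 with BS+AMF, against 24.5 ± 19.7 with BS (SD, n = 3, edgeR adjusted p = 0.0146 and 0.00864). BS+PGPB against PGPB called 0 genes by edgeR (403 at an unadjusted p under 0.05, 0 by DESeq2) and BS+AMF against AMF 0 (2518 and 133). No leaf gene departed from the sum of the components by edgeR for BS+PGPB (470 and 1) or BS+AMF (1190 and 9). Of these unadjusted counts, 403 and 470 lie below a share of 0.05 of the 21311 genes tested, and 2518 and 1190 above it. The fit of the compared groups alone gave 0 genes in all 4 pairwise comparisons, where DESeq2 called 1224 for BS+PGPB and 1702 for BS+AMF against BS. When 1 library was left out, BS+PGPB against BS gave 67 without BS replicate 1, 36 without BS+PGPB replicate 1, 808 without BS replicate 2, 254 without BS+PGPB replicate 2, 119 without BS replicate 3 and 105 without BS+PGPB replicate 3. BS+AMF against BS gave 211 without BS replicate 1, 165 without BS+AMF replicate 1, 256 without BS+AMF replicate 2, 291 without BS replicate 3 and 1601 without BS+AMF replicate 3. BS+AMF against AMF gave 45 without BS+AMF replicate 3, and the departure of BS+AMF from the sum 5 without BS replicate 2 and 1 without AMF replicate 3.

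In leaf under normal conditions, BS+PGPB changed 361 genes, 86 higher and 275 lower, and BS+AMF 92, 26 higher and 66 lower. LOC111909709 rose to 155 ± 62.2 CPM with BS+PGPB from 35.6 ± 24.3 CPM, and LOC111915885 fell to 29.9 ± 9.53 CPM with BS+AMF from 195 ± 88 CPM (SD, n = 3, edgeR adjusted p = 0.0386 and 0.0294). BS called 0 genes by edgeR (883 at an unadjusted p under 0.05, 3 by DESeq2), PGPB 0 (1630 and 8) and AMF 0 (2237 and 3). Of these unadjusted counts, 883 lies below a share of 0.05 of the 21311 genes tested, and 1630 and 2237 above it. The fit of the compared groups alone called 0 genes for each combination, where DESeq2 called 1041 for BS+PGPB and 618 for BS+AMF, and BS+PGPB gave 200 with no filter on low counts. Single left-out libraries changed BS+PGPB to 2 without BS+PGPB replicate 1 or 2 or 3, 2436 without control replicate 1 and 1 without control replicate 2 or 3. BS+AMF gave 30 without BS+AMF replicate 1, 1699 without control replicate 1, 21 without BS+AMF replicate 2, 0 without control replicate 2 or 3 and 3 without BS+AMF replicate 3. PGPB gave 220 without control replicate 1, AMF 640 without control replicate 1, and BS 1 without BS replicate 2.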

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

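The tests of the replicates that lay apart, of the calls of salt-stressed roots against the normal control, of a change of the single-treatment effects with salt, and of a shared plant lot were chosen only after the results were seen.

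The response to salt differed between treatments in 1 leaf gene and 9 root genes by edgeR's test of the interaction. The leaf gene, LOC111879943, had a salt-minus-normal log2 difference of -1.11 in control plants, -2.04 with AMF and 1.43 with BS+AMF (adjusted p = 0.0426), and 28 of 36 runs with 1 library left out changed that count, to 0 or, without normal BS replicate 2, to 2. The root genes were LOC111902035, LOC111907267, LOC111877455, LOC111898118, LOC111907025, LOC111878957, LOC111918659, LOC111880374 and LOC111902166. LOC111902035 had the smallest adjusted p, 0.000897, and was at 175 ± 52.8 CPM in normal PGPB and 30.2 ± 5.76 CPM in salt PGPB (SD, n = 3).

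The 9 root genes follow a wider pattern. There are 2047 ways to part the 12 groups of a tissue in 2. The set of normal and salt BS+PGPB, normal and salt BS+AMF and salt PGPB was set apart by 129 root genes, 68 higher and 61 lower. The next of the 792 sets of 5 groups had 15 and the next set of more than 1 group 61. This set was taken as that of more than 1 group with the most such root genes, so its rank in root is no test. It was set apart by 9 leaf genes, where those sets had 0 and 1, but single groups reached 146 genes in root (normal BS+AMF) and 20 and 11 in leaf (normal BS and salt BS), and no gene was shared between the organs (0). The summed root-predominant genes also had their lowest root group means in these 5 groups, 11050 to 13160 CPM against 14160 to 18740 CPM in the other 7. Single libraries overlapped, with 15640 CPM in normal BS+PGPB replicate 3 and 12650 CPM in normal BS replicate 2. A plant lot or genotype shared by the 5 groups is a candidate explanation. PGPB against control under salt was the only contrast used for this test. There, the median leaf change of the 120 root genes also tested in leaf was 0.192 of their median root change. In leaf, 83 went in the same direction and 3 were called, a share near the 2.01% called over all leaf genes. The genes were chosen for no overlap between these groups in root, which inflates the root change and lowers the ratio. A shared lot stays open, and a lot cannot be told apart from the groups because no batch is labelled. An effect of the treatments themselves and a difference in root makeup also stay open, as untested.

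Leaf normal control replicate 1 and the pair of replicates 2 and 3 lay apart, at a mean correlation of 0.882 against 0.981 within the pair, with scores of -53.1, 110.6 and 97.6 on the leading leaf component; salt BS+AMF replicate 3 lay as far from its replicates, at 0.901 and 0.856 against 0.958, and without it BS+AMF against BS under salt called 1601 genes in place of 907. The total of replicate 1, 16.4 M counts, and those of the pair lie within the 14.8 to 18.3 M of the other leaf libraries, which argues against library size. Root-predominant genes summed to 5.60, 2.90 and 6.20 CPM in replicates 1 to 3, below the 17.8 CPM reached by another leaf library. Those genes were chosen for a low mean level in these same 3 libraries, which limits their sums in advance. The sums therefore cannot argue against RNA from root, which stays open. A wrong label within the leaf set could account for either part, since replicate 1 correlated most with the salt control, at 0.966, and the pair with it at 0.905, but 29 of 36 leaf libraries lay closer to another group than to their own. Which of the 3 is out of place stays open, and no biological explanation was tested.

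In root, the single treatments called more genes under salt than under normal conditions. A position of the salt control libraries apart from the rest could be one source, and against the normal control the median change kept 0.643 (BS), 0.844 (PGPB) and 0.658 (AMF) of its size, with the same direction in 1398 of 1402, 2562 of 2574 and 774 of 777 genes. The salt control alone was set apart from all other root groups by 94 genes, 41 higher and 53 lower. For the normal control this number was 52, and for normal BS+AMF 146. Against the normal control 220 (BS), 2823 (PGPB) and 190 (AMF) genes were called, but both contrasts share the treated libraries, which can keep part of a median, and the second holds the salt effect too, so neither the medians nor these counts exclude the position of the salt control, which stays open for all 3. A change of the effect with salt could be the other source, and its test over all genes called 2 genes for BS, 38 for PGPB and 0 for AMF by edgeR, which leaves a change of the effect with salt open. Over the genes called under salt, the median log2 change in their direction was 0.87 (BS), 0.75 (PGPB) and 0.80 (AMF) under salt and -0.048, 0.16 and 0.29 under normal conditions, and 1196, 1068 and 13 passed the test adjusted over those genes alone, but they were chosen for their change under salt, which inflates these gaps and counts.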

How the results depend on the processing

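The fit of the compared groups alone and the mean salt effect were chosen after the data were seen. No named gene reversed direction in any alternative, the runs with 1 library left out included. The choice of genes with no overlap between the compared libraries all but fixed this, so it is no test of the named genes. Of 165 named values, all 165 were called with DESeq2 size factors, 139 with no filter, 146 with the replicate block and 156 with DESeq2 (the others had no DESeq2 adjusted p), against 60 of the 156 tested in the fit of the compared groups alone. Each named value was tested in 6 runs with 1 library left out, and over all these runs it stayed past the threshold 535 times and did not 455 times, with the same direction. The cause of each change below was not tested, except that the fit of 2 groups uses fewer libraries and leaving out 1 library leaves fewer. With the replicate number as a block (replicate block), counts in leaf were 3 for mean salt effect (from 0) and 0 for interaction (from 1). In root they were 7 for PGPB, normal (from 11) and 1 for departure of BS+PGPB, salt (from 2). The block moved no other count by over 1.5 times, those of the 5 comparisons treated as paired included. That choice rests on the correlations of same-numbered libraries alone. The labels do not say whether libraries were paired in these or in the other 25 comparisons. DESeq2 size factors gave in leaf 33 for mean salt effect (from 0). With no filter on low counts there were in leaf 200 for BS+PGPB, normal (from 361), 0 for interaction (from 1) and in root 6 for PGPB, normal (from 11). The DESeq2 Wald test gave in leaf 12 for salt in control plants (from 0), 3 for BS, salt (from 0), 996 for PGPB, salt (from 429), 3 for AMF, salt (from 0), 1471 for BS+PGPB, salt (from 601), 1679 for BS+AMF, salt (from 927), 3 for BS, normal (from 0), 8 for PGPB, normal (from 0), 3 for AMF, normal (from 0), 1041 for BS+PGPB, normal (from 361), 618 for BS+AMF, normal (from 92), 1224 for BS+PGPB against BS, salt (from 451), 1702 for BS+AMF against BS, salt (from 907), 133 for BS+AMF against AMF, salt (from 0), 1 for departure of BS+PGPB, salt (from 0), 9 for departure of BS+AMF, salt (from 0), 608 for mean salt effect (from 0) and in root 2 for salt in control plants (from 0), 2621 for BS, salt (from 1402), 1695 for AMF, salt (from 777), 3 for BS, normal (from 0), 52 for PGPB, normal (from 11), 283 for AMF, normal (from 14), 779 for BS+PGPB against BS, salt (from 289), 20 for BS+PGPB against PGPB, salt (from 0), 1035 for BS+AMF against BS, salt (from 644), 305 for BS+AMF against AMF, salt (from 101), 70 for departure of BS+PGPB, salt (from 2), 604 for departure of BS+AMF, salt (from 101), 1742 for mean salt effect (from 1021). The DESeq2 likelihood ratio test gave in leaf 29 for interaction (from 1) and in root 431 for interaction (from 9). The fit of the compared groups alone gave in leaf 1 for BS, salt (from 0), 0 for PGPB, salt (from 429), 0 for BS+PGPB, salt (from 601), 0 for BS+AMF, salt (from 927), 0 for BS+PGPB, normal (from 361), 0 for BS+AMF, normal (from 92), 0 for BS+PGPB against BS, salt (from 451), 0 for BS+AMF against BS, salt (from 907) and in root 3 for salt in control plants (from 0), 0 for BS, salt (from 1402), 1102 for PGPB, salt (from 2574), 236 for AMF, salt (from 777), 1 for BS, normal (from 0), 0 for PGPB, normal (from 11), 1 for AMF, normal (from 14), 1523 for BS+AMF, normal (from 3324), 7 for BS+PGPB against BS, salt (from 289), 3 for BS+AMF against BS, salt (from 644), 19 for BS+AMF against AMF, salt (from 101). Leaf counts with 1 library left out ran from 0 to 640 for AMF, normal, 0 to 1187 for mean salt effect, 0 to 2 for interaction, 0 to 1 for BS, normal and 0 to 1699 for BS+AMF, normal. Further leaf ranges were 1 to 2436 for BS+PGPB, normal, 0 to 3810 for salt in control plants, 0 to 220 for PGPB, normal, 0 to 1 for AMF, salt and 0 to 45 for BS+AMF against AMF, salt. Further leaf ranges were 0 to 5 for departure of BS+AMF, salt, 0 to 1 for BS, salt, 36 to 808 for BS+PGPB against BS, salt, 165 to 1601 for BS+AMF against BS, salt and 0 in every run for departure of BS+PGPB, salt. Further leaf ranges were 119 to 1194 for BS+AMF, salt, 0 to 622 for BS+PGPB, salt, 0 in every run for BS+PGPB against PGPB, salt and 0 to 629 for PGPB, salt. Root counts with 1 library left out ran from 0 to 99 for AMF, normal, 615 to 1558 for mean salt effect, 2 to 14 for interaction, 0 in every run for BS, normal and 1698 to 2947 for BS+AMF, normal. Further root ranges were 2199 to 3415 for BS+PGPB, normal, 0 in every run for salt in control plants, 0 to 40 for PGPB, normal, 42 to 634 for AMF, salt and 33 to 159 for BS+AMF against AMF, salt. Further root ranges were 29 to 259 for departure of BS+AMF, salt, 71 to 1845 for BS, salt, 76 to 296 for BS+PGPB against BS, salt, 165 to 747 for BS+AMF against BS, salt and 1 to 7 for departure of BS+PGPB, salt. Further root ranges were 1726 to 4182 for BS+AMF, salt, 2467 to 4614 for BS+PGPB, salt, 0 in every run for BS+PGPB against PGPB, salt and 1242 to 3290 for PGPB, salt. The tests of the 39 lists fixed before the data were examined were not run, as none matched a gene. Depths of 13.9 to 18.3 M counts and 3 libraries per group limit what is detected.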

Other observations

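All tests of the chloroplast gene lists were chosen after the data were seen, as was the mean salt effect among the split counts; the split counts of the other comparisons were planned.

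No call of a chloroplast gene list in leaf held with an estimated correlation (smallest adjusted p = 0.324 with an estimated correlation). With BS+PGPB under normal conditions, 26 of 27 chloroplast-encoded photosynthesis genes had a positive log2 change in leaf, with a median of 1.41 (0.74 without normal BS+PGPB replicate 1, and up to 1.81 without another library), and 1 rose over all genes tested, psaC, which encodes an iron-sulfur subunit of photosystem I, by 3.36 on the log2 scale (edgeR adjusted p = 0.0432). Adjusted over the list alone, 7 rose, against 0 without normal BS+PGPB replicate 1, 0 without normal control replicate 3, 1 without normal control replicate 2 and 11 without normal BS+PGPB replicate 3. psaC passed over all genes tested in 1 of the 6 runs with 1 library left out, that without normal control replicate 1. The camera set test gave an adjusted p of 9.48e-07 with a preset correlation of 0.01, and an adjusted p of 0.49 with an estimated correlation. For the mean salt effect in leaf, 26 of 27 were positive with a median of 0.76 and 17 rose adjusted over the list alone (camera adjusted p = 4.25e-11, and adjusted p = 0.324 with an estimated correlation), against 7 without salt BS replicate 3 and 12 to 22 without any other library. Chloroplast genes took a median of 0.0215% of leaf counts and 0.00308% of root counts, so few reads lie behind these values. Single libraries stood apart, with 0.0561% in normal BS+PGPB replicate 1 against 0.0238% and 0.0176% in the other replicates, 0.0945% in salt BS replicate 3 and 0.0861% in salt PGPB replicate 3. Their mitochondrial shares were 0.00245%, 0.0102% and 0.00562%, against 0.000394% and 0.000304% in the other normal BS+PGPB replicates. psaC also rose with PGPB in salt-stressed leaf, by 2.82 (edgeR adjusted p = 0.0396), and passed in 0 of the 6 runs with 1 library left out. In root, rps3 and matK fell by 2.15 and 2.30 with BS+AMF under normal conditions (edgeR adjusted p = 0.0389 and 0.0131). These genes were named after their values were seen.

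For each pairwise comparison the 6 libraries were split in all 10 ways, which cannot give a share under 0.1. In leaf, 1 of the 10 splits, the real one, reached the real count in these comparisons, given as the real count against the highest of the others: 429 against 0 for PGPB, salt, 601 against 0 for BS+PGPB, salt, 927 against 2 for BS+AMF, salt, 361 against 0 for BS+PGPB, normal, 92 against 11 for BS+AMF, normal, 451 against 0 for BS+PGPB against BS, salt. In leaf, 2 of the 10 splits did so for 1 comparison: 907 against 1964 for BS+AMF against BS, salt. Where the real leaf count was 0, all 10 splits reached it: 0 against 2073 for salt in control plants, 0 against 1 for BS, salt, 0 against 0 for AMF, salt, 0 against 2108 for BS, normal, 0 against 3436 for PGPB, normal, 0 against 2591 for AMF, normal, 0 against 0 for BS+PGPB against PGPB, salt, 0 against 966 for BS+AMF against AMF, salt. In root, 1 of the 10 splits, the real one, reached the real count in these comparisons, given as the real count against the highest of the others: 1402 against 0 for BS, salt, 2574 against 0 for PGPB, salt, 777 against 0 for AMF, salt, 4744 against 0 for BS+PGPB, salt, 3522 against 0 for BS+AMF, salt, 11 against 0 for PGPB, normal, 14 against 0 for AMF, normal, 4253 against 0 for BS+PGPB, normal, 3324 against 1 for BS+AMF, normal, 289 against 0 for BS+PGPB against BS, salt, 644 against 13 for BS+AMF against BS, salt, 101 against 0 for BS+AMF against AMF, salt. Where the real root count was 0, all 10 splits reached it: 0 against 0 for salt in control plants, 0 against 0 for BS, normal, 0 against 2 for BS+PGPB against PGPB, salt. The leaf splits with 2073, 2108, 3436, 2591 and 966 genes against a real count of 0 point to a structure of the libraries whose cause was not tested.

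For the contrasts over more groups, 100 arrangements of the labels were drawn, and the number with as many called genes, the real one included, was 100 of 100 for departure of BS+PGPB, salt in leaf (0 against 14), 100 of 100 for departure of BS+AMF, salt in leaf (0 against 652), 4 of 100 for interaction in leaf (1 against 461), 100 of 100 for mean salt effect in leaf (0 against 1268), 3 of 100 for departure of BS+PGPB, salt in root (2 against 2603), 2 of 100 for departure of BS+AMF, salt in root (101 against 2864), 3 of 100 for interaction in root (9 against 105) and 1 of 100 for mean salt effect in root (1021 against 12), with the real count against the highest other in brackets. For the mean salt effect the condition labels were permuted within each treatment, which moves condition differences into the spread within groups. For root, at a share of 0.05, this excludes only that condition made no difference in any treatment. A difference in 1 treatment alone, whatever its source, could give the same share. For the interactions and departures the treatment labels were permuted within each condition, which moves the treatment effects into the spread within groups, so these shares neither exclude chance nor show it. Where the real count is 0 every arrangement reaches it, and nothing follows. The arrangements with several times the real count point to a structure of the libraries, of which the treatments are a part.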
